A study of Mus musculus with 8 samples.

How the data were processed

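Bulk RNA-seq was measured in 8 libraries of sorted mouse T follicular helper (Tfh) cells, the CD4+ T cells that help B cells in germinal centres. Per the labels, the cells came from K/BxN mice, a strain with spontaneous autoimmune arthritis, that carried a fate-mapping reporter which leaves the fluorescent protein ZsGreen in cells that had been in the Th17 state. CD4+ T cells were enriched by negative selection from Peyer's patch, the lymphoid tissue of the small intestine, and from spleen. Tfh cells were then sorted as CD4+, TCRβ+, CXCR5+, PD-1+ and CD25-negative, and divided into ZsGreen+ and ZsGreen− cells. RNA was extracted with Trizol. The library notes name a poly A enrichment or a non-directional ultra-low-input mRNA preparation without saying which library had which. Reads of overlapping genes on opposite strands cannot be separated in a non-directional library.

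The 4 groups had 2 libraries each, replicate 1 from the tables of experiment 1 and replicate 2 from those of experiment 2. Nothing in the labels says that the replicates come from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical in part. The replicates are not repeats of the same RNA, at least in spleen ZsGreen−, where Y-linked genes had 0 counts in replicate 1 and 397 in replicate 2. Pairing by experiment was checked on the values: deviations from the group means correlated across genes between libraries of the same experiment with r from 0.825 to 0.867 over 6 pairs of groups, and genes are not independent replicates.

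The raw tables hold estimated read counts (expected counts) per gene, as deposited, since 17.6% to 29.9% of the values in a library lay more than 0.01 from a whole number. The normalized tables deposited by the authors hold a signal, which is these counts multiplied by 1 constant per library, within a relative deviation of 9.17e-06, with factors from 0.765 to 1.58 that were set separately in each experiment. Partek, STAR, DESeq2 and the genome build mm39 are named in the submitters' processing notes, and versions and settings are not given in the sources used here. The estimated counts were rounded and used for every test, and the signal was used for this check and for 1 alternative. The tables held 18114 genes in experiment 1 and 20397 in experiment 2. The 16735 genes in both were used. Those in 1 table only held at most 0.0597% of a library's counts in experiment 1 and 0.597% in experiment 2.

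edgeR 4.0.16 in R 4.3.3 tested 14418 genes after its filterByExpr filter by group (minimum count 10, minimum total 15), which removed 2317. Library sizes were scaled by TMM, with factors from 0.656 to 1.24. A quasi-likelihood model with robust dispersion had a mean for each of the 4 groups and a term for the experiment, leaving 3 residual degrees of freedom. The contrasts were ZsGreen+ over ZsGreen− in each tissue, their mean, their difference, and Peyer's patch over spleen in each sort. Adjusted p-values are from edgeR's two-sided quasi-likelihood F test with Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. Expression levels are TMM-scaled CPM. Log2 CPM values, used for principal components, correlations between libraries and contrasts within an experiment, have a prior count of 2. Log2 fold changes are those of the fitted model, and their standard error (SE) was derived from the F statistic. Genes were also counted by the study's own signature criterion, a fold change of at least 1.5 at an unadjusted p under 0.05, since the adjustment behind its p is not given in the sources used here. Overlaps between tissues were tested with two-sided Fisher's exact tests across genes.

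There were 23 gene lists with 360 symbols, of which 340 were in both tables and 328 were tested. They covered the Th17, Tfh, Th1 and cytotoxic, Th2, and Treg and Tfr programs, naive and central memory T cells, homing and tissue residence, proliferation, immediate early and TCR-induced genes, inhibitory receptors, and cytokines and cytokine receptors. Others held interferon-stimulated genes, glycolysis and hypoxia, cholesterol synthesis, oxidative phosphorylation, heat shock and dissociation stress. The remaining lists were markers of B cells, plasma cells, myeloid cells, CD8 T and NK cells, γδ T cells and ILC, epithelial cells, and stromal and erythroid cells. Each list was tested with fry (direction on balance) and with camera (against the other genes, preset correlation 0.01, and again with an estimated correlation) from limma 3.58.1, with Benjamini-Hochberg adjustment over the lists in a contrast. The lists, the contrasts, the thresholds, the experiment term and the rule for named genes were set before the data were examined.

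By that rule 13 genes of the sorts and programs were always named, including Il17a, Il17f, Ccr6, Cxcr5, Pdcd1, Bcl6, Il21, Icos, Maf, Batf, Il2ra and Cd4. Added to these were the 12 largest and 12 smallest log2 fold changes of each sort contrast and the 8 largest and 8 smallest of the others. These had an adjusted p under 0.05, a mean of at least 5 CPM and the same sign in both experiments, and were filled up by p from the study's criterion. Unnamed gene models, receptor and immunoglobulin segments, mitochondrial and ribosomal protein genes were left out of that choice. Up to 4 members of each list with the smallest p were added. Some genes that the rule names are not reported here. Where all libraries of a group had 0 counts, a fold is a lower bound against a floor of 3 counts per library, and with 1 to 3 counts it is a ratio with an exact 95% interval. Shares of counts carry Wilson 95% intervals. These intervals and floors cover counting error only. The floor was between 0.16 and 0.46 CPM.

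Alternatives were RLE size factors, DESeq2 1.42.0, no count filter, a stricter filter (at least 10 CPM in 2 libraries), no experiment term, the 4 compared libraries alone, leaving out receptor, mitochondrial and ribosomal protein genes, leaving out each library, and the mean log2 ratio within an experiment of the deposited signal (pseudocount 1), which has no test. Among the scaling alternatives the largest shift of the median of all genes was -0.04 on the log2 scale. Tested on simulated data with the study's counts, edgeR recovered 41.8% of 2-fold and 77.3% of 4-fold changes in the Peyer's patch contrast and 34.3% and 74.2% in the spleen contrast. True calls at 1.5, 2 and 4-fold were 5, 28 and 51 in Peyer's patch and 4, 23 and 49 in spleen. False calls among unchanged genes were 13 and 16, a larger share of all calls than the adjusted threshold of 0.05 aims at. A simulated 2-fold shift of the Th17 list in spleen had a fry adjusted p of 0.00495 and 0.014 by camera with an estimated correlation, with 0 of the other 22 lists past the threshold by either. Genes were drawn independently of each other in this simulation. In the spleen data camera estimated correlations of 0.503 within the Tfh list and 0.72 within the proliferation list. False calls in such lists were therefore not tested. Exon lengths and overlaps came from GENCODE M21 (GRCm38), matched by Ensembl identifier, and gene positions came from the deposited tables on mm39. Of 244 named genes, 31 shared exon sequence with another gene and 13 shared at least 10% of it, among them Foxp3, Tdrkh, Vcl, Hopx, Sh2d1a, Nrn1, Atp1b1, Gpr15, Fdft1, Cox5a, Syp, Ndufb5 and Abcb1a. The partner had the larger mean count per library for Vcl (Ap3m1, 601 against 94), Gpr15 (Cpox, 552 against 51), Nrn1 (Fars2, 280 against 129) and Fdft1 (Ctsb, 12978 against 600).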

Results

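Messenger RNA was profiled in ZsGreen+ and ZsGreen− Tfh cells of Peyer's patch and spleen, 4 groups of 2 libraries, to find the genes that mark Tfh cells with a Th17 past. Total estimated counts per library (replicates 1 and 2) were 14965393 and 10843208 for Peyer's patch ZsGreen− cells, 14403458 and 13787974 for Peyer's patch ZsGreen+ cells, 15234833 and 10009823 for spleen ZsGreen− cells, and 15323743 and 14298133 for spleen ZsGreen+ cells. In every group replicate 1 belongs to experiment 1 and replicate 2 to experiment 2. The experiments separated on the first principal component of log2 CPM, which held 66.4% of the variance. The second held 14.7% and separated the tissues, and the third held 8.07% and separated ZsGreen+ from ZsGreen− libraries. Across genes, which are not independent replicates, log2 levels correlated with r from 0.928 to 0.978 within an experiment (12 pairs of libraries) and from 0.792 to 0.851 between experiments (16 pairs). Mitochondrial genes took 2.7% to 6.04% of the counts of a library, ribosomal protein genes 1.83% to 5.46%, and the 10 most abundant genes 4.61% to 20%.

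**Figure D1:**
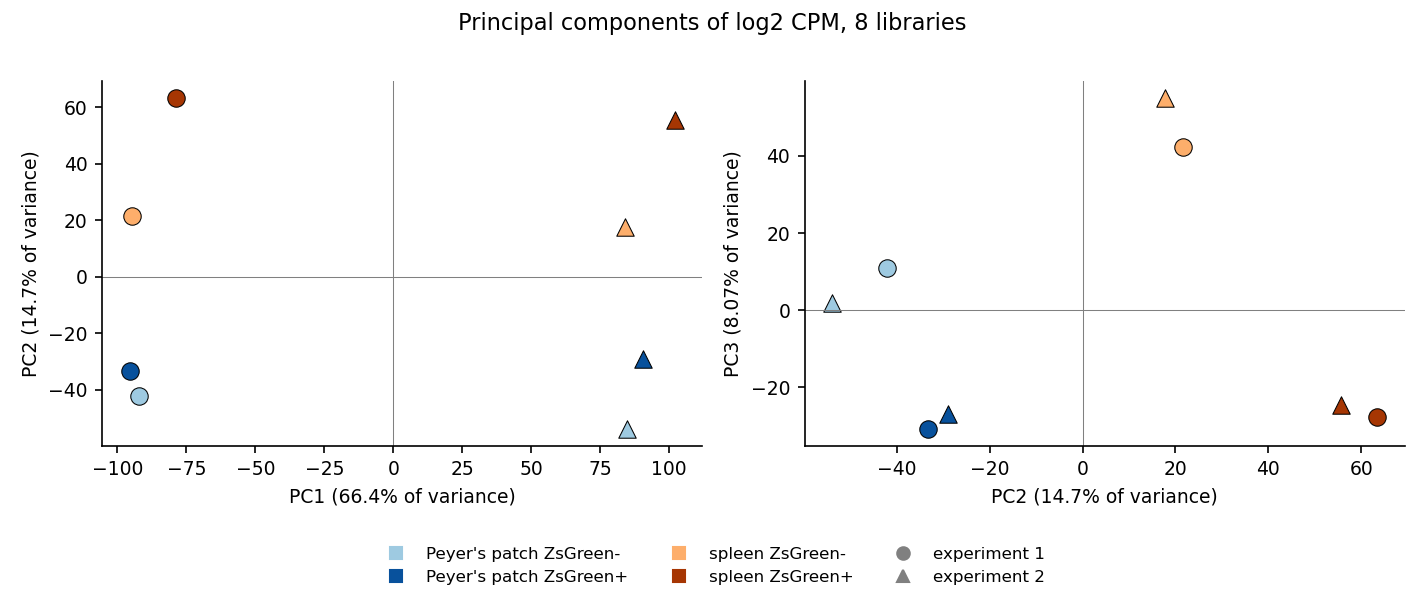
Principal components of log2 CPM over the 14418 genes tested, with the first component against the second on the left and the second against the third on the right; each point is 1 of 8 libraries, coloured by group and shaped by experiment. The first component (66.4% of the variance) parts the experiments, the second (14.7%) the tissues and the third (8.07%) the ZsGreen sorts.

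The first comparison, ZsGreen+ against ZsGreen− cells of Peyer's patch, asks which genes form the signature of Th17-derived Tfh cells in the gut. ZsGreen+ cells had more mRNA for Il17re, a subunit of the IL-17C receptor, at 16.5 ± 7.25 CPM (SD, n = 2) against 2.64 ± 0.0326, a log2 fold change of 2.54 ± 0.24 (SE, adjusted p = 0.000938). Il23r, a subunit of the receptor for IL-23, which sustains Th17 cells, rose by 3.29 ± 0.28 (adjusted p = 0.000526). Ccr6, the receptor for CCL20, rose by 2.31 ± 0.20 (adjusted p = 0.000613), and Cxcr6, a chemokine receptor of tissue-resident T cells, by 1.70 (adjusted p = 0.0482). Lower in ZsGreen+ cells were Eomes, a transcription factor of cytotoxic and memory T cells, by -4.80 (adjusted p = 0.00397). So was Foxp3, the regulatory T cell factor, by -3.25 (adjusted p = 0.0118). Each of these genes had the same sign in both experiments. Of the 32 genes named past the threshold in Peyer's patch, Ccr6, Il23r and Il17re passed with any library left out. Eomes lost its call without replicate 1 of either Peyer's patch group, and Foxp3 without these or without replicate 2 of Peyer's patch ZsGreen−. Cxcr6 lost it when any library except replicate 1 of Peyer's patch ZsGreen+ was left out (highest adjusted p 0.255 for Eomes, 0.242 for Foxp3 and 0.205 for Cxcr6).

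The Tfh genes of Peyer's patch did not pass the test. Cxcr5, whose protein is a sort marker, had a log2 fold change of -0.31 ± 0.16 (adjusted p = 0.687), with 634 ± 2.53 CPM in ZsGreen+ and 784 ± 24.7 in ZsGreen− cells. Pdcd1, which encodes PD-1, had 0.10 (adjusted p = 0.971), Bcl6, the defining transcription factor of Tfh cells, 0.04 (adjusted p = 0.988). The cytokine gene Il21 had 0.59 (adjusted p = 0.747) and the costimulatory receptor gene Icos 0.36 (adjusted p = 0.735). Maf had 0.36 (adjusted p = 0.609), Batf 0.25 (adjusted p = 0.75), Il2ra, which encodes CD25, 0.30 (adjusted p = 0.915) and Cd4 -0.18 (adjusted p = 0.887). The Th17 cytokine genes had large but variable values: Il17f 2.98 ± 0.41 (adjusted p = 0.065) and Il17a 4.42 ± 1.35 (adjusted p = 0.546). Il17a had 0.562 and 11.7 CPM in the ZsGreen+ libraries of experiments 1 and 2, and 0 and 0.554 in the ZsGreen− libraries.

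Across all genes tested in Peyer's patch, 41 rose and 22 fell, all 63 with the same sign in both experiments and a median absolute log2 fold change of 1.77. At an unadjusted p under 0.05 there were 1172 genes, where 721 are expected by chance, and 380 higher and 281 lower genes met the study's criterion. Further genes among the 12 largest increases taken by the naming rule were Tmem176a (2.94), Plekhf1 (2.56), Adam12 (2.20), Xkrx (2.14), Nrgn (1.86), the water channel gene Aqp3 (1.83) and Tdrkh (1.77), the last of which shares 36.7% of its exon length with Oaz3. Oaz3 had a mean count of only 3 against 156 for Tdrkh. The decreases included Actg2 (-2.62), the transcription factor Sox4 (-2.24 ± 0.30, adjusted p = 0.00821), Cd22 (-1.77), the IL-10 receptor gene Il10ra (-1.55), Abcb9 (-1.32), Gpr83 (-1.20), Bmp7 (-1.14), Abcb1a (-1.11), Actn1 (-1.08), Izumo1r (-0.94) and Chn2 (-0.89). The 63 calls were 18 (11 up, 7 down) without replicate 2 of Peyer's patch ZsGreen−, 46 up and 7 down without replicate 1 of Peyer's patch ZsGreen+, and 147 (81 up, 66 down) by DESeq2. Without replicate 1 of Peyer's patch ZsGreen− edgeR called 7 up and 0 down, with 342 lower at an unadjusted p under 0.05 and 19 lower by DESeq2. The 281 lower genes by the study's criterion were 452 without replicate 2 of Peyer's patch ZsGreen−, 535 without replicate 2 of Peyer's patch ZsGreen+ and 150 with the stricter count filter.

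**Figure D2:**
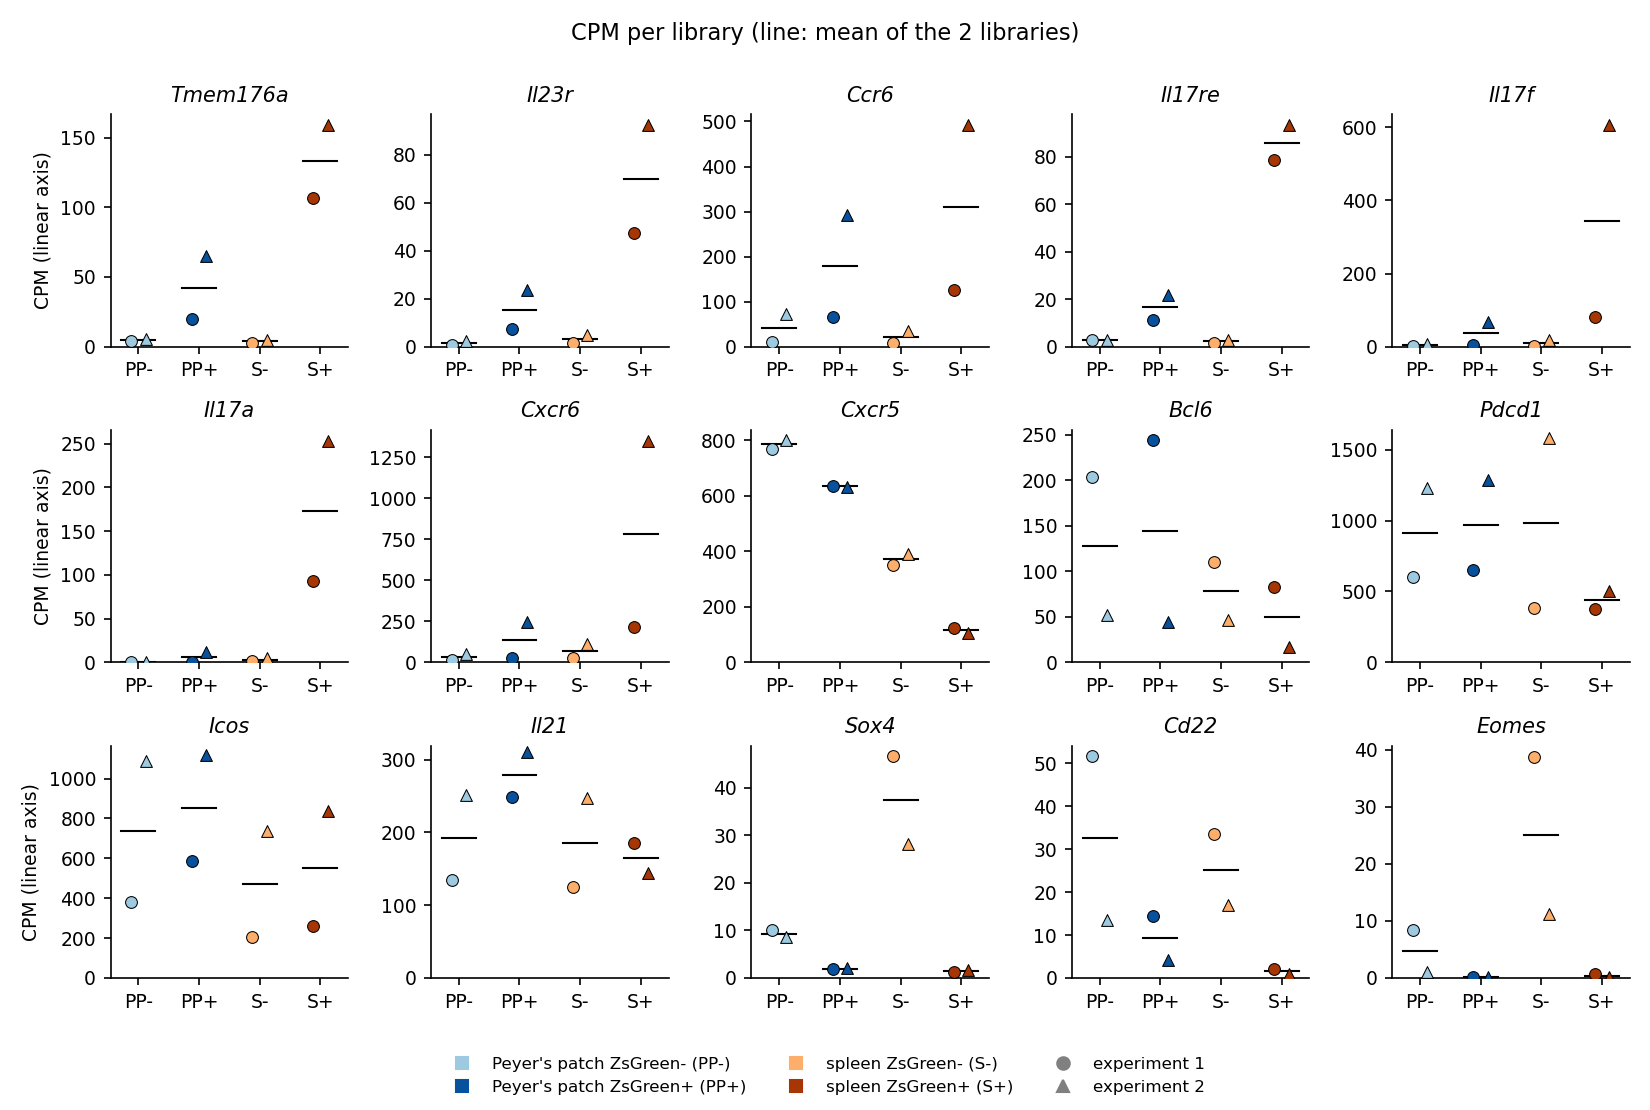
CPM (linear axes) of 15 genes in each of the 8 libraries, by group; points are libraries, their shape gives the experiment, and lines are means of 2. Il17re has a mean of 16.5 CPM in Peyer's patch and 86 in spleen ZsGreen+ cells against 2.64 and 2.16 in ZsGreen− cells, and Cxcr5 is lowest in spleen ZsGreen+ cells at 114 CPM.

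Of the 14 Th17 genes tested in Peyer's patch, 5 rose, including Il23r, Il17re and Ccr6, and none fell, or 14 when adjusted over the list alone. The list rose on balance (fry adjusted p = 0.0297, camera adjusted p = 2.06e-62, adjusted p = 0.0264 with an estimated correlation). Of 14 naive and central memory genes 2 fell, including Actn1, or 7 adjusted over the list alone. That list fell on balance by fry (adjusted p = 0.0297) and camera (adjusted p = 1.42e-13, adjusted p = 0.0761 with an estimated correlation). In the Th1 and cytotoxic list of 17, Il18r1 (1.33) and Il18rap (1.54), which form the IL-18 receptor, rose and Eomes and Ccl5 (-2.08) fell, with 2 up and 6 down adjusted over the list alone (fry adjusted p = 0.566). Foxp3 and Gpr83 fell among 12 Treg and Tfr genes (2 adjusted over the list alone, fry adjusted p = 0.456). Il10ra and Il21r (-0.80) fell among 23 cytokine and receptor genes, or 3 adjusted over the list alone (fry adjusted p = 0.456, camera adjusted p = 9.87e-05, adjusted p = 0.514 with an estimated correlation). Cxcr6 rose among 18 homing genes (1 adjusted over the list alone), and Kit (1.41) among 8 γδ T cell and ILC markers (2 up and 1 down adjusted over the list alone). No member was called by edgeR in the other 16 lists. Among their 219 tested members 31 had an unadjusted p under 0.05, where 11 are expected by chance, and DESeq2 called 2. Over all 14418 genes tested 1172 had such a p, where 721 are expected, so an excess is not particular to these lists. Of these lists, the 22 Tfh genes had 1 up and 1 down at an unadjusted p under 0.05 and 0 adjusted over the list alone (fry adjusted p = 0.948). The 23 proliferation genes had 13 at an unadjusted p under 0.05 and 8 adjusted over the list alone, all higher in ZsGreen+ cells (fry adjusted p = 0.456, camera adjusted p = 2.07e-12, adjusted p = 0.514 with an estimated correlation). The 19 interferon-stimulated genes had 1 lower adjusted over the list alone (camera adjusted p = 4.68e-08, adjusted p = 0.514 with an estimated correlation), and glycolysis 1 higher of 18. Adjusted over the list alone, 0 members passed in the lists for Th2 (6 tested), immediate early (22), inhibitory receptor (9), cholesterol synthesis (16), oxidative phosphorylation (20), heat shock (11), B cell (14), plasma cell (8), myeloid (12), CD8 T and NK (5), epithelial (7), and stromal and erythroid genes (7).

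In spleen, the same sort comparison asks for the signature outside the gut. Spleen ZsGreen+ cells had 86 ± 10.5 CPM of Il17re (SD, n = 2) against 2.16 ± 0.633 in ZsGreen− cells, a log2 fold change of 5.36 ± 0.26 (SE, adjusted p = 1.71e-06). The Th17 cytokine genes Il17f (5.66 ± 0.39, adjusted p = 0.000775) and Il17a (6.26 ± 0.77, adjusted p = 0.0231) rose, as did Csf2, which encodes GM-CSF (5.33, adjusted p = 0.000184). Il23r rose by 4.57 ± 0.25 (adjusted p = 4.8e-06), Ccr6 by 3.88 ± 0.21 (adjusted p = 5.51e-06) and Il1r1, the receptor for IL-1, by 2.37 (adjusted p = 3.29e-05). Cxcr5 fell to 114 ± 13.7 CPM from 370 ± 27.4, a log2 fold change of -1.70 ± 0.17 (adjusted p = 0.000127). The largest decrease among the genes taken by the naming rule was that of Gzmk, a granzyme gene, with -7.49 ± 0.60 (adjusted p = 3.3e-05), followed by Eomes (-5.96, adjusted p = 2.21e-05).

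Il2ra rose in spleen by 2.03 ± 0.39 (adjusted p = 0.0088) although the sort took CD25-negative cells, and the AP-1 factor gene Batf by 0.60 (adjusted p = 0.0375). Not past the threshold were Bcl6 (-0.92, adjusted p = 0.0921), Pdcd1 (-0.88, adjusted p = 0.16), Il21 (-0.07, adjusted p = 0.941), Icos (0.25, adjusted p = 0.556), Maf (0.04, adjusted p = 0.913) and Cd4 (-0.29, adjusted p = 0.421). The 12 largest increases taken by the naming rule also held Pde5a (5.30), Fam167a (5.29), Tmem176a (5.14), Vax2 (5.12), Tmem176b (5.03), Ltb4r1 (4.73), a receptor for the chemoattractant leukotriene B4, and Lilr4b (4.66). Cxcl3, a neutrophil-attracting chemokine gene, was at least 42.2-fold higher, with 325 counts in ZsGreen+ and 0 in ZsGreen− libraries. The largest decreases taken by the naming rule also held Gal (-5.83), the chemokine gene Ccl5 (-4.78), Sox4 (-4.63 ± 0.31, adjusted p = 9.41e-06), Cd22 (-4.15), Tns1 (-3.71), Ifi214 (-3.15), Nrn1 (-3.04), Igfbp4 (-2.97) and Atp1b1 (-2.90). Nrn1 and Atp1b1 share 22.3% and 18.7% of their exon length with Fars2 and Nme7.

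Across all genes tested in spleen, 653 rose and 590 fell, 1241 of the 1243 with the same sign in both experiments. Their median absolute log2 fold change was 1.04, 3158 genes had an unadjusted p under 0.05 where 721 are expected by chance, and 923 higher and 1077 lower genes met the study's criterion. The count of 1243 was 487 without replicate 2 of spleen ZsGreen+, 591 without its replicate 1, and 510 without replicate 2 of spleen ZsGreen−, and the 653 that rose were 390 without replicate 1 of spleen ZsGreen−. Of the 74 genes named past the threshold in spleen, 43 passed with any library left out, including Ccr6, Il23r, Il17re, Il17f, Csf2, Cxcr5, Sox4, Gzmk and Eomes. Il17a lost its call when replicate 1 or 2 of spleen ZsGreen− or replicate 2 of Peyer's patch ZsGreen− was left out (highest adjusted p 0.26). Il2ra lost it without replicate 2 of spleen ZsGreen− or replicate 1 of spleen ZsGreen+ (highest 0.131), and Batf without replicate 1 of spleen ZsGreen− or either replicate of spleen ZsGreen+ (highest 0.302).

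Of the 14 Th17 genes tested in spleen, 13 rose (14 adjusted over the list alone, fry adjusted p = 0.00441, camera adjusted p = 1.25e-72, adjusted p = 0.0203 with an estimated correlation). Of 23 proliferation genes, 20 rose and none fell (23 adjusted over the list alone), among them the mitotic kinesin gene Kif11 (1.38, adjusted p = 0.000908), Rrm2 (1.49), Birc5 (1.47) and Cenpe (1.60). That list had a fry adjusted p of 0.0757 and a camera adjusted p of 2.88e-29, with adjusted p = 0.339 with an estimated correlation. Of 22 Tfh genes 10 fell and 1 rose (12 and 1 adjusted over the list alone). Cxcr5, Id3 (-1.62), Slamf6 (-1.18) and Cebpa (-1.95) had the smallest p among those that fell, and Batf was the member that rose. The Tfh list had a fry adjusted p of 0.135 and a camera adjusted p of 3.61e-08, with adjusted p = 0.391 with an estimated correlation. Of 14 naive and central memory genes 10 fell and 1 rose (11 and 2 adjusted over the list alone, fry adjusted p = 0.0149, camera adjusted p = 7.91e-14, adjusted p = 0.11 with an estimated correlation), including Ccr7 (-1.88), Nsg2 (-1.58) and Actn1 (-1.66). Of 19 interferon-stimulated genes 9 fell (17 adjusted over the list alone), such as Usp18 (-1.48) and Ifit1 (-1.22), with a fry adjusted p of 0.128 and a camera adjusted p of 1.93e-09, and adjusted p = 0.391 with an estimated correlation. Of 16 cholesterol synthesis genes 5 rose (9 adjusted over the list alone), including Sqle (1.06) and Mvd (1.17), with a fry adjusted p of 0.0692 and a camera adjusted p of 7.96e-06, and adjusted p = 0.339 with an estimated correlation.

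Single members of other lists also passed the threshold in spleen. Among 12 Treg and Tfr genes Il2ra rose and 5 fell, including Foxp3 (-1.90) and Ikzf2 (-1.73), with the same numbers adjusted over the list alone (fry adjusted p = 0.0572, camera adjusted p = 0.0255, adjusted p = 0.339 with an estimated correlation). Il18r1 (1.05) and Il18rap (1.59) rose and 3 Th1 and cytotoxic genes fell out of 17, with 2 and 5 adjusted over the list alone (fry adjusted p = 0.135, camera adjusted p = 0.00471, adjusted p = 0.391 with an estimated correlation). The homing receptor genes Cxcr6 (3.39) and Ccr9 (3.43) and the tissue residence gene Rgs1 (1.81) rose. Itgb1, the integrin β1 gene, fell (-2.52), among 18 homing and tissue residence genes (5 up and 1 down adjusted over the list alone). Cytokines and receptors had 5 up and 4 down of 23 (6 and 4 adjusted over the list alone), and inhibitory receptors 2 up (Cd160 1.08, Tnfrsf9 0.54) and 1 down (Tigit -0.73) of 9 (2 and 2 adjusted over the list alone). Slc2a3 (0.94) and Pgk1 (0.61) rose among 18 glycolysis genes (2 adjusted over the list alone). Ccr4 (1.14) rose among 6 Th2 genes (1 up and 1 down adjusted over the list alone) and Uqcrfs1 (0.58) among 20 oxidative phosphorylation genes (1 adjusted over the list alone). Among markers of other cells, the B cell genes Mef2b (-2.30) and Ighm (-1.39) fell out of 14 (3 down and 1 up adjusted over the list alone). Blk (4.63) and Kit (1.69) rose while Trdc, the constant region of the δ receptor chain, fell (-2.29) out of 8 γδ T cell and ILC markers (3 and 1 adjusted over the list alone). The plasma cell gene Ighg1 rose (2.66; 1 of 8, also adjusted over the list alone) on counts of experiment 1 only. No member was called by edgeR in the other 6 lists (immediate early, heat shock, myeloid, CD8 T and NK, epithelial, stromal and erythroid), where 6 of 64 members had an unadjusted p under 0.05 and DESeq2 called 4.

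**Figure D3:**
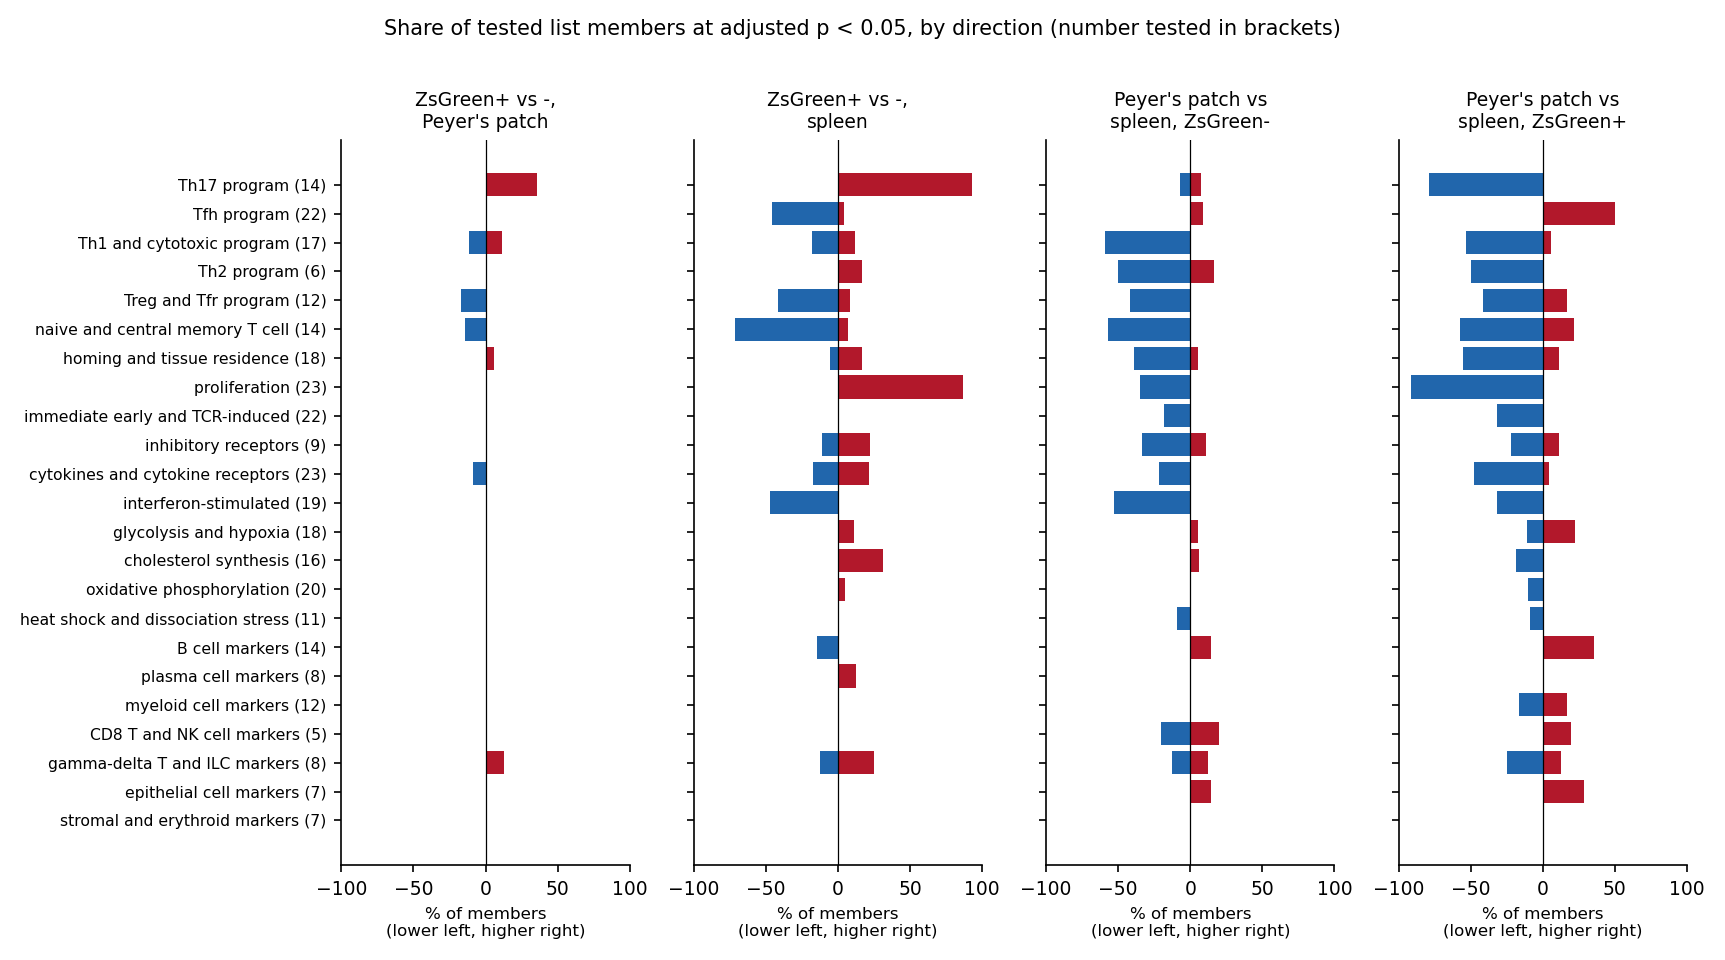
Percentage of the tested members of each of the 23 gene lists that passed an adjusted p of 0.05, to the right for higher and to the left for lower values, in 4 contrasts (ZsGreen+ over ZsGreen− in each tissue and Peyer's patch over spleen in each sort). In spleen 13 of 14 Th17 and 20 of 23 proliferation genes are higher in ZsGreen+ cells, and 11 of 22 Tfh genes are higher in Peyer's patch than in spleen ZsGreen+ cells.

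The sort signatures of the tissues overlapped. By the study's criterion 219 genes were higher in ZsGreen+ cells of both tissues, where 24.3 would be expected for independent lists (Fisher's exact test across genes, p = 3.80e-166). Another 169 were lower in both, where 21 would be expected (Fisher's exact test, p = 3.33e-119). The shared genes made up 57.6% of the higher and 60.1% of the lower genes of Peyer's patch, and 23.7% and 15.7% of those of spleen. The share of the lower genes was 38.1% without replicate 2 of Peyer's patch ZsGreen− and 29.5% without replicate 2 of Peyer's patch ZsGreen+, and 106 lower genes were shared without replicate 1 of Peyer's patch ZsGreen−. By adjusted p, 37 of the 41 genes that rose in Peyer's patch also rose in spleen and 21 of the 22 that fell also fell there. Across genes, which are not independent replicates, the log2 fold changes of the tissues correlated with r = 0.425 over all genes, 0.787 over those called in spleen and 0.865 over those called in Peyer's patch. The change was larger in spleen for 1213 of the 1243 genes called there, with a median ratio of 0.339 of Peyer's patch to spleen, and for 49 of the 63 called in Peyer's patch, with a median ratio of 0.756. Each of these sets was chosen in the tissue named, which favours larger values in that tissue.

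The mean of both tissues averages their sort contrasts, so a gene can pass through a large change in a single tissue. Ccr6 (3.09, adjusted p = 9.96e-07) rose, as did Batf (0.42, adjusted p = 0.0358), while Cxcr5 fell (-1 ± 0.12, adjusted p = 0.000355). Ccr6 had passed in each tissue, but Batf and Cxcr5 in spleen only. The 8 largest increases taken by the naming rule were Il17a (5.34), Ltb4r1 (4.83), Mmp25 (4.60), Il17f (4.32), Pde5a (4.20), Tmem176a (4.04), Igfbp7 (3.99) and Il17re (3.95). The 8 largest decreases taken by it included Gzmk (-5.90), Eomes (-5.38), Sox4 (-3.44), Ccl5 (-3.43), Cd22 (-2.96), Nrn1 (-2.83) and Actg2 (-2.67). In all, 646 genes rose and 596 fell, with a median absolute log2 fold change of 0.727, and 3200 genes had an unadjusted p under 0.05. Of the 21 genes named past the threshold for the mean, 18 passed with any library left out, and Il17a, Il2ra (1.17) and Batf did not. The total of 1242 was 547 without replicate 1 and 703 without replicate 2 of Peyer's patch ZsGreen−, 806 without replicate 2 of spleen ZsGreen−, and 708 and 763 without replicates 1 and 2 of spleen ZsGreen+. The 596 that fell were 338 and 369 without replicates 1 and 2 of Peyer's patch ZsGreen+.

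The difference of the sort contrast between the tissues asks whether the signature depends on the tissue. Il17re rose more in spleen than in Peyer's patch, with a difference (Peyer's patch minus spleen) of -2.81 ± 0.36 (SE, adjusted p = 0.0172), and so did Il1r1 (-1.71 ± 0.26, adjusted p = 0.0338). Among the genes past the threshold, the adhesion receptor gene Adgrg5 had the largest difference, -3.76 ± 0.33 (adjusted p = 0.00145), from values of -0.28 in Peyer's patch and 3.48 in spleen. Itgb1 differed by 2.63 ± 0.35 (adjusted p = 0.0338), from values of 0.11 and -2.52. Cxcr5 (1.39 ± 0.23, adjusted p = 0.0578) and Ccr6 (-1.56, adjusted p = 0.0658) did not pass. In all, 4 genes had a positive and 10 a negative difference, with 1223 at an unadjusted p under 0.05 and 144 calls by DESeq2. The balance of directions depended on the fit, since 90 were positive and 46 negative with the Y-linked level as a covariate, chosen after seeing the data. In the passage that follows, the edgeR count is given with libraries left out. The edgeR count of the difference was 2 without replicate 1 and 4 without replicate 2 of Peyer's patch ZsGreen−, and 3 and 80 without replicates 1 and 2 of Peyer's patch ZsGreen+. It was 93 without replicate 1 of spleen ZsGreen− and 23 without replicate 1 of spleen ZsGreen+, and of the 12 genes past the threshold that the rule names, only Adgrg5 passed with any library left out. Of the 14 Th17 genes 2 were lower in this difference, or 9 adjusted over the list alone (fry adjusted p = 0.095, camera adjusted p = 1.44e-22, adjusted p = 0.0992 with an estimated correlation). Of the 22 Tfh genes edgeR called 0, with 9 at an unadjusted p under 0.05, 3 by DESeq2 and 8 adjusted over the list alone (fry adjusted p = 0.528, adjusted p = 0.622 with an estimated correlation). Of the 23 proliferation genes it called 0, with 13 lower at an unadjusted p under 0.05, 0 by DESeq2 and 10 adjusted over the list alone (adjusted p = 0.622 with an estimated correlation).

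**Figure D4:**
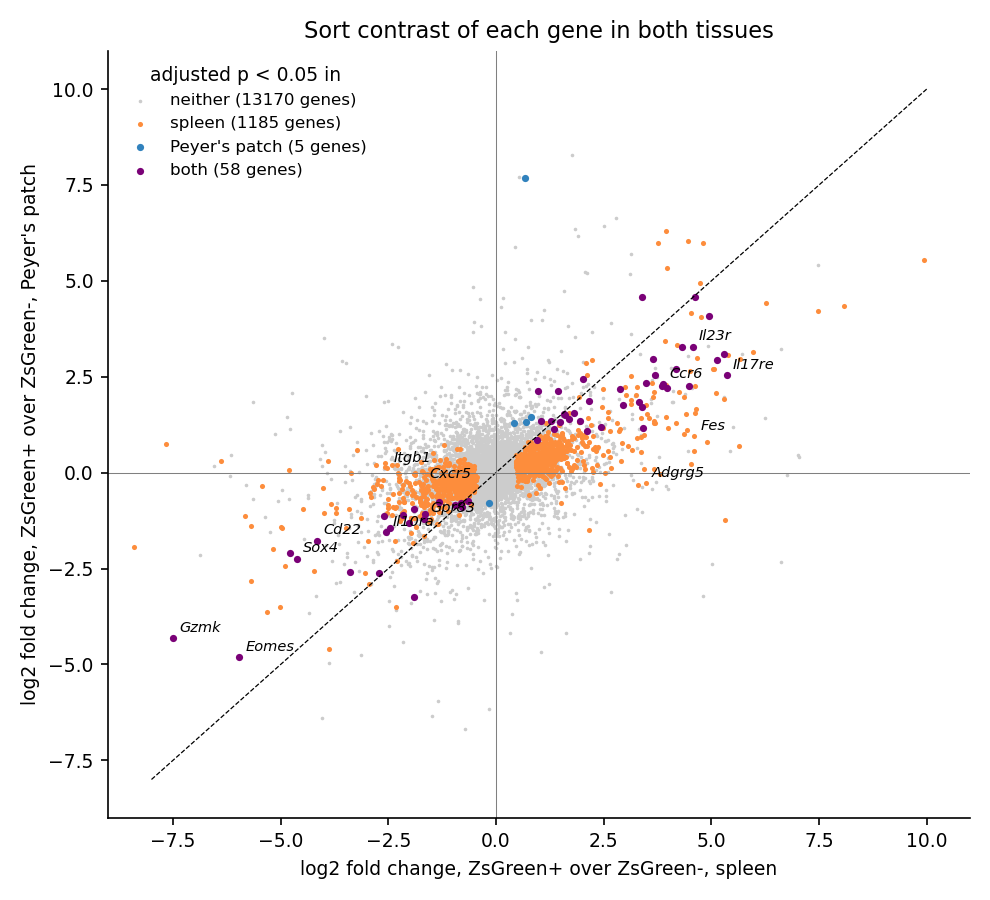
Log2 fold change of ZsGreen+ over ZsGreen− cells in spleen (horizontal axis) against Peyer's patch (vertical axis) for the 14418 genes tested, coloured by the tissue in which the adjusted p was under 0.05; the dashed line marks equal values. Of the 1243 genes called in spleen, 1213 have the larger absolute value in spleen, and r across all genes is 0.425.

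Peyer's patch against spleen in ZsGreen− cells asks which genes differ between the tissues in sorted cells without the reporter's label. Cxcr5 was higher in Peyer's patch by 1.08 ± 0.16 (SE, adjusted p = 0.00229), at 784 ± 24.7 CPM against 370 ± 27.4 (SD, n = 2). Klf2, a factor that keeps T cells in circulation, was lower there by -3.32 (adjusted p = 1.25e-05). Lower too were S1pr1, the receptor for exit from lymphoid tissue, by -1.92, and Ccr7 by -2.29. Itgb1 was lower by -4.67 ± 0.28 (adjusted p = 3.87e-05), Nrp1 by -6.01 (adjusted p = 0.00228) and Foxp3 by -2.88. Bcl6 (0.53, adjusted p = 0.371), Pdcd1 (0.07, adjusted p = 0.952), Icos (0.71, adjusted p = 0.0855) and Ccr6 (0.71, adjusted p = 0.0714) did not pass. Among the genes taken by the naming rule, which have a mean of at least 5 CPM, the largest increases in Peyer's patch were Osbpl6 (3.52 ± 0.29, adjusted p = 4.57e-05), H2-Eb1 (3.24), Adgrg5 (3.20), Hey1 (3.03), Fads2 (2.98), Syp (2.87), Klhl4 (2.84) and the B cell factor Pax5 (2.78). Those higher in spleen, besides Nrp1 and Itgb1, were Gcg (-5.51), Nrn1 (-5.39), Lmna (-4.92), Spp1 (-4.92), Zbtb32 (-4.81) and Atf3, whose spleen level was 77.5 times that of Peyer's patch (exact 95% interval 26.2 to 379). Il1rl1 was at least 28.2-fold lower in Peyer's patch.

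Of the 17 Th1 and cytotoxic genes 10 were lower in Peyer's patch than in spleen ZsGreen− cells (13 down and 1 up adjusted over the list alone), such as Il18r1 (-1.89), Ccl5 (-3.36) and Hopx (-1.45). That list had a fry adjusted p of 0.0145 and a camera adjusted p of 3.18e-24 (adjusted p = 0.0515 with an estimated correlation). Of 14 naive and central memory genes 8 were lower (9 adjusted over the list alone, fry adjusted p = 0.0101, camera adjusted p = 1.22e-19, adjusted p = 0.0515 with an estimated correlation). Of 18 homing genes 7 were lower and 1 higher (10 and 2 adjusted over the list alone, fry adjusted p = 0.0145, camera adjusted p = 7.53e-09, adjusted p = 0.0515 with an estimated correlation), among them Gpr15 (-4.36) and S1pr4 (-1.04). Gpr15 shares 12.5% of its exon length with Cpox, which had a mean count of 552 against 51 for Gpr15. Of 12 Treg and Tfr genes 5 were lower (6 adjusted over the list alone, fry adjusted p = 0.0101, camera adjusted p = 6.12e-09, adjusted p = 0.0515 with an estimated correlation), including Prdm1 (-3.29) and Capg (-1.75). Interferon-stimulated genes had 10 of 19 lower (12 adjusted over the list alone, camera adjusted p = 1.31e-11, adjusted p = 0.28 with an estimated correlation). Immediate early genes had 4 of 22 lower (7 adjusted over the list alone, camera adjusted p = 1.18e-11, adjusted p = 0.28 with an estimated correlation). Proliferation genes had 8 of 23 lower (17 adjusted over the list alone, camera adjusted p = 3.68e-11, adjusted p = 0.28 with an estimated correlation). Of the 14 B cell markers Pax5 and H2-Eb1 were higher (7 adjusted over the list alone, camera adjusted p = 9.98e-07, adjusted p = 0.28 with an estimated correlation). Fabp2 was at least 13.9-fold higher, as 1 of 7 epithelial markers (5 adjusted over the list alone, fry adjusted p = 0.0467, camera adjusted p = 1.78e-05, adjusted p = 0.243 with an estimated correlation). Heat shock and dissociation stress genes had 1 of 11 lower (5 adjusted over the list alone, fry adjusted p = 0.127, camera adjusted p = 2.99e-05, adjusted p = 0.28 with an estimated correlation). Th2 genes had 3 of 6 lower and 1 higher (4 and 1 adjusted over the list alone, fry adjusted p = 0.0437, camera adjusted p = 0.000596, adjusted p = 0.156 with an estimated correlation). Of 8 plasma cell markers edgeR called 0, with 3 at an unadjusted p under 0.05 and 3 by DESeq2, and 3 higher adjusted over the list alone (camera adjusted p = 0.000948, adjusted p = 0.183 with an estimated correlation). In all, 262 genes were higher and 530 lower in Peyer's patch, with a median absolute log2 fold change of 1.21 and 2555 genes at an unadjusted p under 0.05. Of the 64 genes named past the threshold here, 35 passed with any library left out, among them Cxcr5, Klf2, Itgb1 and Foxp3. The total of 792 was 319 without replicate 1 and 313 without replicate 2 of Peyer's patch ZsGreen−, and the 262 higher were 103 without replicate 1 of spleen ZsGreen−.

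Peyer's patch against spleen in ZsGreen+ cells asks the same of sorted cells with the reporter's label. Here Il17re was lower in Peyer's patch by -2.44 (adjusted p = 2.5e-05), at 16.5 ± 7.25 CPM against 86 ± 10.5 (SD, n = 2). Also lower were Il23r (-2.34), Il17f (-3.59, adjusted p = 0.00127), Il17a (-5.33, adjusted p = 0.019) and Ccr6 (-0.85, adjusted p = 0.0107). Csf2 was 703 times as high in spleen (exact 95% interval 126 to 27800). Cxcr5 was higher in Peyer's patch by 2.47 ± 0.17 (adjusted p = 1.07e-05) and Bcl6 by 1.49 (adjusted p = 0.0111). Icos (0.82, adjusted p = 0.0266) and Maf (0.60, adjusted p = 0.0321) were higher too, while Pdcd1 (1.04, adjusted p = 0.0742) did not pass. Il2ra was lower in Peyer's patch (-2.27, adjusted p = 0.00294). The largest increases among the genes taken by the naming rule were Pax5 (4.62 ± 0.44, adjusted p = 5.55e-05), Osbpl6 (4.52), Pgam2 (4.38), Hpgds (3.68), Spsb1 (3.63), Mef2b (3.48), Ntn1 (3.38) and Cpeb1 (3.36). Higher in spleen were also Nrp1 (-5.57), Tppp3 (-5.04), Ccrl2 (-4.84), Vcl (-4.71), Cxcl3 (-4.64) and Atf3, which was at least 72.5-fold lower in Peyer's patch. Vcl shares 25.5% of its exon length with Ap3m1, which had a mean count of 601 against 94 for Vcl.

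Of the 14 Th17 genes 11 were lower in Peyer's patch than in spleen ZsGreen+ cells (13 adjusted over the list alone, fry adjusted p = 0.00727, camera adjusted p = 4.92e-19, adjusted p = 0.0575 with an estimated correlation). Of 22 Tfh genes 11 were higher (14 up and 2 down adjusted over the list alone, fry adjusted p = 0.0562, camera adjusted p = 4.96e-10, adjusted p = 0.292 with an estimated correlation), including Cebpa (2.66), Sh2d1a (1.72) and Pou2af1 (0.92). Sh2d1a shares 26.6% of its exon length with Tenm1, which had a mean count of only 1 against 4069 for Sh2d1a. Proliferation genes had 21 of 23 lower (22 adjusted over the list alone, fry adjusted p = 0.0271, camera adjusted p = 1.59e-28, adjusted p = 0.177 with an estimated correlation), such as Kif11 (-1.94), Birc5 (-1.67) and Aurka (-1.77). Of 18 homing genes 10 were lower and 2 higher (the same numbers adjusted over the list alone, fry adjusted p = 0.0112, camera adjusted p = 3.13e-09, adjusted p = 0.0787 with an estimated correlation), among them Itgb7 (-1.79), Cxcr6 (-2.64) and Selplg (-1.63). Cytokines and receptors had 11 of 23 lower and Il6st (1.71) higher (13 and 1 adjusted over the list alone, fry adjusted p = 0.0271, camera adjusted p = 1.07e-06, adjusted p = 0.218 with an estimated correlation). Of 14 B cell markers 5 were higher (7 adjusted over the list alone, camera adjusted p = 2.58e-06, adjusted p = 0.32 with an estimated correlation). Of 7 epithelial markers 2 were higher (4 adjusted over the list alone, camera adjusted p = 0.00278, adjusted p = 0.292 with an estimated correlation). Of 12 myeloid markers Lyz2 (1.89) and Cd68 (1.77) were higher and Itgam (-3.25) and Cst3 (-0.67) lower (4 and 2 adjusted over the list alone). In all, 794 genes were higher and 1034 lower in Peyer's patch, with a median absolute log2 fold change of 1.12 and 3804 genes at an unadjusted p under 0.05. Of the 84 genes named past the threshold here, 56 passed with any library left out, among them Il17re, Il17f, Cxcr5 and Kif11, but Il17a, Ccr6, Bcl6, Icos and Maf did not (highest adjusted p 0.0915, 0.124, 0.0708, 0.387 and 0.28). The total of 1828 was 863 without replicate 1 of Peyer's patch ZsGreen+, and 1051 and 918 without replicates 1 and 2 of spleen ZsGreen+, and the 794 higher were 514 without replicate 2 of Peyer's patch ZsGreen+. Between the sorts, 188 genes higher in Peyer's patch were shared, where 14.4 would be expected for independent lists, and 365 higher in spleen, where 38 would be expected.

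Members of other lists also passed the threshold between the tissues in ZsGreen+ cells, though not every list passed as a whole. In Peyer's patch 9 of 17 Th1 and cytotoxic genes were lower and 1 higher (12 and 1 adjusted over the list alone, fry adjusted p = 0.0112, camera adjusted p = 5.52e-11, adjusted p = 0.11 with an estimated correlation), such as Il18r1 (-1.61) and Il18rap (-2.57). Of 14 naive and central memory genes 8 were lower and 3 higher (the same numbers adjusted over the list alone), among them Klf2 (-3.03) and S1pr1 (-1.93), with a fry adjusted p of 0.0112 and a camera adjusted p of 1.07e-06 (adjusted p = 0.11 with an estimated correlation). Treg and Tfr genes had 5 of 12 lower and 2 higher (6 and 2 adjusted over the list alone, fry adjusted p = 0.0112, camera adjusted p = 0.000675, adjusted p = 0.124 with an estimated correlation), including Foxp3 (-4.22) and Prdm1 (-2.63). Th2 genes had 3 of 6 lower (4 adjusted over the list alone, fry adjusted p = 0.0112, camera adjusted p = 7.65e-05, adjusted p = 0.11 with an estimated correlation), among them Gata3 (-0.98). Of 22 immediate early genes, a list that holds Atf3, 7 were lower (10 adjusted over the list alone, fry adjusted p = 0.0919, camera adjusted p = 9.81e-09, adjusted p = 0.32 with an estimated correlation), including Nr4a2 (-3.82) and Fosl2 (-2.23). Among 11 heat shock and dissociation stress genes 1 was lower, Hsph1 (-0.52, adjusted p = 0.0188), which lost its call without either replicate of Peyer's patch ZsGreen+ or of spleen ZsGreen+ (highest adjusted p 0.125). That list had 4 lower adjusted over the list alone (fry adjusted p = 0.132, camera adjusted p = 0.00433, adjusted p = 0.388 with an estimated correlation). Interferon-stimulated genes had 6 of 19 lower (9 down and 1 up adjusted over the list alone, fry adjusted p = 0.154, camera adjusted p = 0.00173, adjusted p = 0.503 with an estimated correlation). Of 8 plasma cell markers edgeR called 0, with 3 at an unadjusted p under 0.05, 2 by DESeq2 and 0 adjusted over the list alone (fry adjusted p = 0.0334, camera adjusted p = 0.0842). Inhibitory receptors had 1 higher and 2 lower of 9, glycolysis 4 and 2 of 18, and γδ T cell and ILC markers 1 and 2 of 8. Cholesterol synthesis had 3 lower of 16, oxidative phosphorylation 2 lower of 20, and the CD8 T and NK markers 1 higher of 5. Adjusted over the list alone these 6 lists had 2 up and 3 down, 4 and 2, 1 and 2, 2 and 5, 0 and 2, and 1 and 2 (lowest fry adjusted p 0.132).

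**Figure D5:**
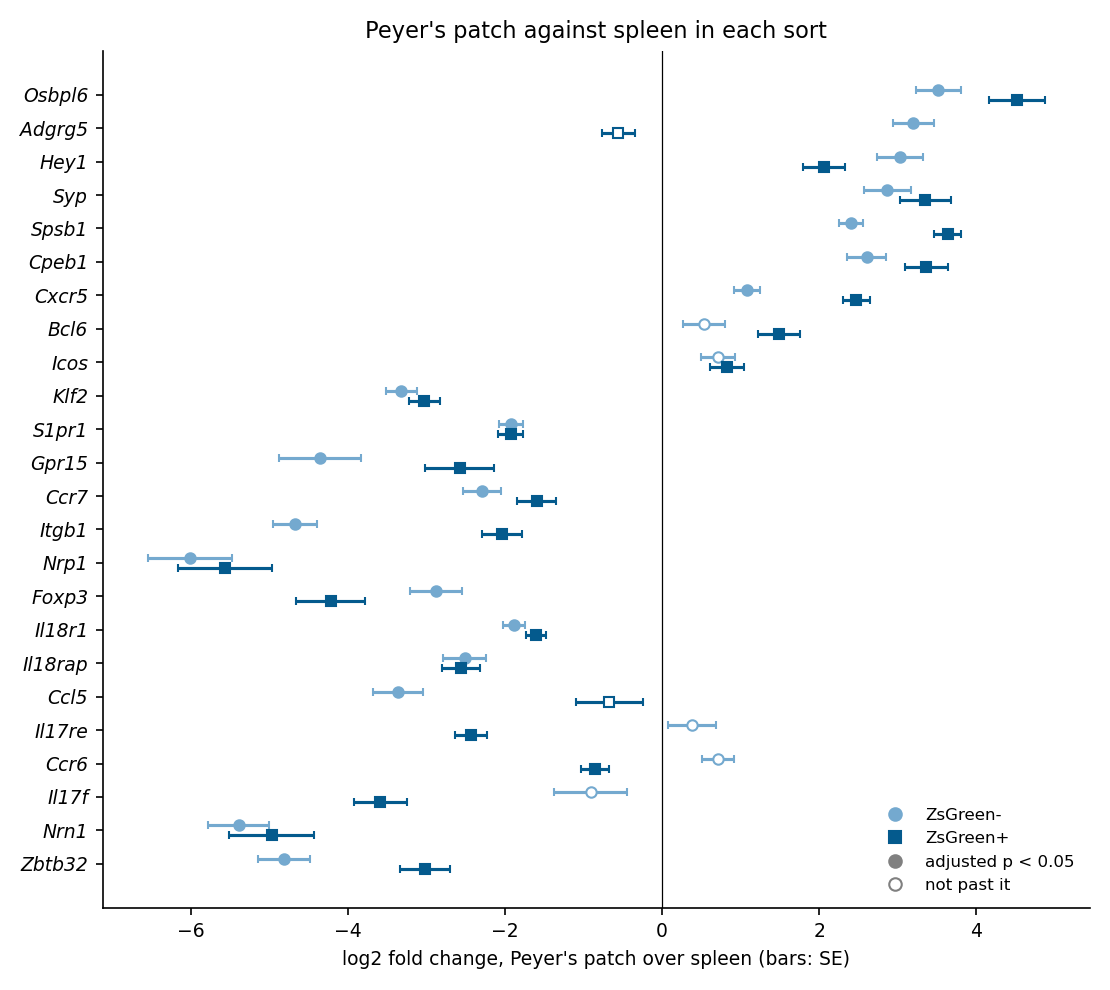
Log2 fold change of Peyer's patch over spleen with its SE for 24 genes in ZsGreen− and in ZsGreen+ cells, with filled points for an adjusted p under 0.05. Klf2 lies at -3.32 in ZsGreen− and -3.03 in ZsGreen+ cells, and Cxcr5 at 1.08 and 2.47.

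The key genes lie on mm39, per the submitters' processing notes, at these positions of the deposited tables. Ccr6 (ENSMUSG00000040899) spans chromosome 17 from 8454875 to 8475973, and Il23r (ENSMUSG00000049093) chromosome 6 from 67399916 to 67468839. Il17a (ENSMUSG00000025929) and Il17f (ENSMUSG00000041872) lie on chromosome 1, from 20801129 to 20804720 and from 20847370 to 20860841, and Cxcr5 (ENSMUSG00000047880) on chromosome 9 from 44423084 to 44473174. The level of a gene could differ between the experiments while its contrast kept the sign, as for Ccr6, which had 65 and 293 CPM in Peyer's patch ZsGreen+ cells of experiments 1 and 2, against 9.96 and 72.3 in ZsGreen− cells. In spleen it had 126 and 492 CPM in ZsGreen+ against 8.18 and 35.4 in ZsGreen− cells.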

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

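For the patterns weighed after the gene values, the tests of γδ T cells, of the Y-linked covariate in spleen, of ZsGreen− cells in the ZsGreen+ sort and of the Tfh list were chosen only after the result was seen. Some results were chosen for a closer look because the contrast of ZsGreen+ over ZsGreen− cells differed between the tissues in the test of the difference itself (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Peyer's patch minus spleen, log2 with SE). Adgrg5 differed by -3.76 ± 0.33 (adjusted p = 0.00145; -0.28 in Peyer's patch and 3.48 in spleen). The kinase gene Fes differed by -3.65 ± 0.53 (adjusted p = 0.0335; 0.95 and 4.60). Il17re differed by -2.81 ± 0.36 (adjusted p = 0.0172; 2.54 and 5.36). Furin, a protease gene, differed by -2.38 ± 0.27 (adjusted p = 0.0155; 0.69 and 3.07). Ccdc102a differed by -2.29 ± 0.30 (adjusted p = 0.0172; -0.80 and 1.50), and Acsbg1 by -2.26 ± 0.28 (adjusted p = 0.0172; 1.15 and 3.41). Il1r1 had a difference of -1.71 ± 0.26 (adjusted p = 0.0338; 0.66 and 2.37), and Rbpj, the transcription factor of Notch signalling, -1.61 ± 0.22 (adjusted p = 0.0181; 0.21 and 1.82). Scpep1 had -1.55 ± 0.24 (adjusted p = 0.0338; 0.33 and 1.88), and the glucose transporter gene Slc2a3 -1.46 ± 0.23 (adjusted p = 0.0338; -0.52 and 0.94).

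The other 4 genes had positive differences. Jdp2 had 1.71 ± 0.26 (adjusted p = 0.0338; 0.02 in Peyer's patch and -1.69 in spleen), and Itm2a 1.86 ± 0.25 (adjusted p = 0.018; -0.55 and -2.40). Tgfbr3 had 2.02 ± 0.31 (adjusted p = 0.0338; -0.23 and -2.24) and Itgb1 2.63 ± 0.35 (adjusted p = 0.0338; 0.11 and -2.52).

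In the sort contrast over both tissues, the real split gave 635 genes in a fit with tissue and experiment. The highest of the other splits that part all 4 pairs of sorts gave 0 by edgeR (1506 genes at an unadjusted p under 0.05, against 2932). These 8 splits, of which 1, the real split, gave as many genes, are too few for a share under 0.05. The others of the 33 estimable splits leave pairs whole. Every split but the real one has some of the sort in its spread, which can lower its count. In Peyer's patch, different mixes of male and female mice in experiment 1 are argued against as the whole source: of the 265 autosomal genes at least 2-fold apart there, 171 or 64.5% (exact 95% interval 58.4 to 70.3; 52.7% of the genes under 2-fold apart) lay on the same side in experiment 2, where the Peyer's patch sorts had close Y-linked levels (118 and 111 CPM). The exact interval takes genes as independent replicates, which they are not, and may be too narrow. In spleen, Y-linked levels differed in the same direction in both experiments, so such mixes go with the sort and cannot be told apart from it. With the Y-linked level as a covariate, the fold changes of the 1243 called genes had a median ratio of 1.13 (quartiles 0.961 and 1.3). The median SE went from 0.201 to 0.292 and 574 genes kept their call. The covariate was a log2 level, which set the sorts far apart mainly in experiment 1 (0 and 58.3 CPM, against 60.9 and 105 in experiment 2). The genes were also chosen in the fit without it, so the ratio does not decide. γδ T cells in the ZsGreen+ sorts are argued against by Trdc, which had -2.30 ± 0.34 (adjusted p = 0.0143) over both tissues, and the sort on TCRβ would remove them. Blk (3.09 ± 0.38, adjusted p = 0.000634) and Kit (1.55 ± 0.18, adjusted p = 0.000363) of the same list rose, however. Of its 8 tested members, 4 were higher and 2 lower at an unadjusted p under 0.05 in edgeR's test of the mean. The constant region genes of the γ chain were left out of this check, so it rests on Trdc and the sort alone. A Th17 past of the cells, which the sort was made to select, may be the source and stays open as untested.

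The sort contrast was larger in spleen, with a median ratio of Peyer's patch to spleen log2 fold changes of 0.492 over the genes called for the mean of both tissues. Lower precision in Peyer's patch is argued against by that ratio, since noise alone would not make fold changes smaller on balance. The median SE was 0.2 there and 0.203 in spleen, but the spread of a gene was estimated once over all 8 libraries. The SEs therefore cannot show whether Peyer's patch libraries varied more. ZsGreen− cells in the Peyer's patch ZsGreen+ sort cannot be told apart from a tissue difference: by the median of 646 genes they would have to make up 64.4% of it, so that no gene could lie below -0.63 (log2). Of the 590 genes that fell in spleen, 33 lay below that bound in Peyer's patch by more than 2 SE, or 5.59% (exact 95% interval 3.88 to 7.77), where 5% was allowed for error. That allowance holds only for genes at the bound itself, while the median Peyer's patch value of the 590 was -0.29, so it favours mixing. The interval also takes genes as independent replicates, which they are not, so this share does not decide. In a 1-sided test against the bound, adjusted over the 590, 8 passed, among them Eomes (-4.80), Sox4 (-2.24), Foxp3 (-3.25), Cd22 (-1.77) and Actg2 (-2.62), with 34 at an unadjusted p under 0.05, but 0 passed without replicate 1 of Peyer's patch ZsGreen− (21 unadjusted) or replicate 1 of Peyer's patch ZsGreen+ (18 unadjusted), so that mixing stays open. Nor can cells with less of the Tfh program in the spleen ZsGreen+ sort: the Tfh list had a median difference of 0.901 between the tissues but a fry p of 0.0957, and a biological difference between the tissues stays open as untested.

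The difference between the experiments held the largest share of the variance. Counting noise of genes with few counts is argued against, since the first component held 86.3% of the variance among the 4062 genes with a mean of at least 50 CPM and still separated the experiments. Transcript length may be part of the source, since the ratio of experiment 2 to experiment 1 fell with exon length in every group, with Spearman's rho across 12652 genes (not independent replicates) from -0.475 to a weakest value of -0.397, in a test that could have come out near 0. The median log2 ratio was 0.884 to 1.13 in the shortest quartile of genes and -1.01 to -0.782 in the longest. Which library preparation each experiment had is not given in the sources used here, and no biological explanation was tested.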

How the results depend on the processing

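Without the experiment term edgeR called 0 genes in all 6 contrasts. At an unadjusted p under 0.05 there were then 111, 398, 433, 79, 369 and 568 genes for Peyer's patch, spleen, their mean, their difference, and the tissue contrasts in ZsGreen− and ZsGreen+ cells, fewer than the 721 expected by chance, and DESeq2 called 7, 71, 107, 1, 61 and 136. By the study's criterion there were 72 higher genes in Peyer's patch and 217 in spleen, with 43 shared. Without that term the difference between the experiments enters the spread. DESeq2 gave 147 genes in Peyer's patch (all 63 among them) and 144 for the difference (all 14 among them), and the other contrasts stayed within 1.5 times. The 4 compared libraries alone gave 119 genes in Peyer's patch. For the difference, no count filter gave 47 genes and leaving out receptor, mitochondrial and ribosomal protein genes 28. The stricter filter gave 220 and 610 higher genes by the study's criterion in Peyer's patch and spleen, with fewer genes tested. By adjusted p the overlap of higher genes was 37. The Y-linked covariate, chosen after seeing the data, gave 777 genes in spleen, 703 for the mean and 136 for the difference. Where no reason is given the cause was not tested.

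With a library left out its group has a lone sample, assumed to vary like the other groups. Counts then ran from 7 to 88 in Peyer's patch, 487 to 1357 in spleen, 547 to 1020 for the mean, 2 to 93 for the difference, 313 to 893 for the tissue contrast in ZsGreen− cells and 863 to 1965 in ZsGreen+ cells. The shared higher genes by the study's criterion, chosen for this after seeing the data, ran from 170 to 278. Ighg1 in spleen (2.66) reversed to -3.50 without replicate 1 of spleen ZsGreen− and -1.08 without replicate 1 of spleen ZsGreen+, and was at most 2.87, without replicate 2 of spleen ZsGreen−; all its spleen counts came from experiment 1, and the cause was not tested further.

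Named genes were run with RLE size factors, DESeq2, no experiment term, each library left out and the deposited signal. Of 3157 tested values of named genes past the threshold, 2479 kept their direction and call, 676 kept the direction and lost the call (287 of them without the experiment term), and 2 reversed (Ighg1). Of 2497 tested values of genes not past it, 176 passed. The deposited signal has no test: its mean log2 ratio lay within 1 SE for 271 of 287 values past the threshold (each a named gene in 1 contrast) and further off for 16. Camera kept its side of the threshold for 211 of 276 list results over 2 alternatives, and fry without the experiment term for 129 of 138. With an estimated correlation camera kept its side for 83 and lost its call for 55. Without the experiment term it kept its side for 128, lost its call for 3 and gained it for 7. Lists past the threshold in neither setting count as kept. Depth limits genes near the floor of 0.16 to 0.46 CPM, and 1.5-fold changes were recovered for 7.46% of simulated genes in Peyer's patch and 5.97% in spleen.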

Other observations

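K/BxN T cells carry a transgenic receptor, and the shares of receptor segments are given per library without a measure of diversity. Trbv19 held most of the Trbv segment counts in every library, while the share of the Trav6 family varied widely. Trbv19 held 57.8% (Wilson 95% interval 57 to 58.6) and 81.2% (80.7 to 81.7) of Trbv segment counts in Peyer's patch ZsGreen− cells of experiments 1 and 2, and 70.7% (70.1 to 71.3) and 80.8% (80.4 to 81.2) in ZsGreen+ cells. In spleen it held 63.7% (62.8 to 64.6) and 86.1% (85.7 to 86.6) in ZsGreen− cells, and 77.3% (76.8 to 77.9) and 85% (84.6 to 85.3) in ZsGreen+ cells. Segments of the Trav6 family, whose near-identical copies make assignment to a single member uncertain, held 31% (29.9 to 32.2) and 51.1% (50.1 to 52.2) of Trav counts in Peyer's patch ZsGreen− cells, 30% (28.8 to 31.2) and 61.8% (61 to 62.5) in Peyer's patch ZsGreen+ cells, 48.3% (47.2 to 49.4) and 88.7% (88.3 to 89.1) in spleen ZsGreen− cells, and 58.3% (57.3 to 59.3) and 88.3% (88 to 88.7) in spleen ZsGreen+ cells. The share of Trav6 was higher in spleen than in Peyer's patch in each of the 4 pairs of libraries of the same sort and experiment. Receptor segments took 0.452% to 0.668% of all counts in experiment 1 and 2.71% to 3.2% in experiment 2.

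Genes that serve as markers of other cells were counted too. Igha, the IgA heavy chain gene of mucosal plasma cells, had 244 and 26.8 CPM in Peyer's patch ZsGreen− cells of experiments 1 and 2 and 105 and 61.5 in ZsGreen+ cells, against 6.79 and 0.153, and 7.72 and 0.857, in spleen, and did not pass edgeR's test between the tissues in ZsGreen− (adjusted p = 0.124) or ZsGreen+ cells (adjusted p = 0.0751). Cd79a, a B cell receptor gene, had 5.17 and 0.775 CPM, and 6.47 and 0.675, in Peyer's patch, and at most 0.429 in spleen, and did not pass either (adjusted p = 0.213 and 0.221). Gcg, a hormone gene of intestine and pancreas, had 14.1 and 27.4 CPM in spleen ZsGreen− and 13.8 and 44 in spleen ZsGreen+ cells, against 0.163 and 0.997, and 0.225 and 6, in Peyer's patch. These genes other than Gcg were picked after their values were seen.

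The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 9.74 CPM in Peyer's patch ZsGreen−, 56.8 in Peyer's patch ZsGreen+, 0 in spleen ZsGreen− and 58.3 in spleen ZsGreen+ cells of experiment 1, where the count of 0 allows up to 0.16 CPM. In experiment 2 they had 118, 111, 60.9 and 105 CPM. Xist, expressed from the inactive X chromosome, had 1090, 1390, 1170 and 801 CPM in experiment 1 and 139, 146, 151 and 87.8 in experiment 2, in the same order of groups.

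A pair of genes whose sort contrast differed between tissues are neighbours: Fes lies on chromosome 7 from 80027504 to 80037694 and Furin from 80038333 to 80055184 (mm39). Adgrg5 and Ccdc102a lie on chromosome 8, from 95650322 to 95669908 and from 95629497 to 95644726. Across genes, the contrasts themselves were related to exon length with Spearman's rho of 0.116 in Peyer's patch, -0.0829 in spleen, -0.00888 for their mean and 0.173 for their difference. The median exon length was 3753 bases for the genes that rose and 5151 for those that fell in spleen, 4638 and 4366 in Peyer's patch, 3114.5 and 5471 for the genes with a positive and a negative difference, and 4046.5 for all.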
